A study of Homo sapiens with 14 samples.

How the data were processed

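GATA3 chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in MDA-MB-231, an established triple-negative breast cancer cell line. The labels describe 14 samples: wildtype GATA3 (WT) and the point mutants A442M and G444E, each with and without FLAG on the C-terminal end, and cells with an empty vector, with 2 replicates of each. The 12 samples of the 6 GATA3 groups were analysed. The 2 empty-vector samples were not analysed here, so no background list enters any comparison. Per the labels' protocols the cells were harvested on day 3, an antibody against GATA3 was used in tagged and untagged cells alike, and libraries were made with the Takara ThruPLEX kit. Nothing in the labels says whether replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

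Per the submitters' processing notes, MACS2 2.1.4 and FastQC were used and the genome build was hg38. The aligner, the read depth, the control used for peak calling and the filters are not given in the sources used here. Each deposited list holds one library's peaks, so peaks were called per sample and not on pooled samples. A list has 5 columns without a header: chromosome, start, end, peak name and a score per peak. The deposited score was taken as the authors' own value, on a scale that the files do not name. The titles of the lists speak of 5-fold peaks, so a 5-fold threshold on enrichment is a likely reading, which nothing else in the sources states. It was at least 5.00 in every list and reached 1709, and it was used only to rank or filter peaks within a list. Peak names are numbered with gaps: between 89.1% and 92.0% of the numbers up to the highest were present in each list, so the authors removed peaks before deposit by a rule not given in the sources used here. No read counts came with the lists, so depth is unknown, and no interval on counting error was computed.

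Peaks of the 12 lists (433307 in all) were merged into 78999 regions wherever they overlapped by 1 bp or more. A library called a region when it had a peak there. Regions called in both libraries of one group and in neither of another were counted for 9 pairs of groups, beside the same count for the other ways to divide the 4 libraries. Log2 peak number and shares of peaks were compared by exact permutation tests, two-sided, in 5 contrasts: both mutants, A442M or G444E against WT and A442M against G444E, with genotype labels permuted within the tag state, and FLAG against untagged, with tag labels permuted within genotype. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333, so pairs of groups were not tested alone. The interaction of genotype and tag was tested by permuting tag labels within genotype after the mean tag effect was subtracted. Single regions were tested with Fisher's exact test on calls, 6 FLAG against 6 untagged libraries and 8 mutant against 4 WT libraries, with Benjamini-Hochberg adjustment over regions whose number of calls could reach p = 0.05 at all. Overlap of libraries was measured by the Jaccard index (shared regions over all regions of both) and tested by exact permutation of the pairing, one-sided.

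Genes came from a RefSeq table of GRCh38.p14, whose chromosome coordinates are those of hg38, with 20037 protein-coding genes. The table gives gene spans without strand or exons, so distances were measured to the nearer end of a gene span in place of the transcription start site, and exons, introns and untranslated regions were not assigned. Coordinates are 1-based. The share of peaks at gene ends used 1 kb (5 kb as alternative), and the share near 17 gene lists, written before the data were examined, used 50 kb (10 kb as alternative) with adjustment over the lists of a contrast. Motif shares had been planned and were not run, because no genome sequence was used here.

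Regions were named by the nearest protein-coding gene end within 100 kb, which does not make that gene a target. In 5 comparisons (each mutant against WT in each tag state, and WT-FLAG against WT), regions on one side were ranked by the lower of both libraries' score percentiles, and the 8 highest were named with the 4 highest of the opposite side. The 10 regions with the highest median percentile among those called in all 12 libraries, GATA3, and up to 4 members of each gene list were named as well, the members with the most regions called in 8 or more libraries. Genes named outside this rule are marked, and 2 regions that the rule names are not reported here.

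Labels number the replicates 1 and 2 in every group and do not say what the numbers share. Same-number libraries deviated together: over the 15 pairs of groups, the correlation of the difference between replicate 1 and replicate 2 across regions lay between 0.113 and 0.290. The numbers were therefore taken to pair the samples, from the data and not from the labels, and tests were repeated with labels exchanged only within a number. Alternatives set before the data were examined were a score of at least 10, lists of equal length (the 25248 highest scores of each), regions from 500 bp windows at peak centres, calls that cover at least 50% of the region, a call in at least 1 library, the exchange within replicate numbers, and each library left out in turn. The score took the place of the fold enrichment named in the plan.

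The tests were tried on simulated data. Each changed region was set as called in all libraries of the first side and none of the second, or the reverse. Every other region had the same call probability in all libraries, without group or replicate structure. With 5000 changed regions, 100% were called in both comparisons, with 2.61% false calls for FLAG against untagged and 0.478% for mutant against WT. These shares hold for such clean splits and do not measure power or false calls in the real libraries. With 200 changed regions 0% were called, because a test with so few libraries has too coarse a p-value to pass the adjustment. A count of 0 therefore leaves at least that many changed regions open, and numbers between 200 and 5000 were not simulated. In the data, 230 regions called in all FLAG and no untagged libraries did not pass either. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.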

Results

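GATA3, a zinc-finger transcription factor of luminal breast epithelium, was mapped by ChIP-seq in MDA-MB-231 cells with wildtype GATA3 or the point mutants A442M and G444E. According to the design text, the C-terminal FLAG tag stabilises GATA3 whatever the mutation, so each genotype was compared untagged and with the tag. The 6 groups had 2 libraries each. Peak lists held between 25248 and 51694 peaks, and the number of reads behind them is unknown.

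The tag went with longer peak lists in every genotype. FLAG libraries had 1.30-fold as many peaks as untagged ones, a rise of 0.38 in log2 against a replicate SD of 0.18 (exact permutation test, p = 0.0185 over 216 arrangements, higher in 6 of 6 same-number pairs). Wildtype GATA3 gave 27069 ± 2575 peaks untagged and 40081.5 ± 4422 with the tag (SD, n = 2 each), a ratio of 1.48. A442M gave the longest lists in both states, 37889 ± 2561 untagged and 47343.5 ± 6153 with the tag. G444E gave 29063 ± 3022 and 35207.5 ± 7328.

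A442M lists were longer than WT and G444E lists in each same-number pair, and G444E lists were not set apart from WT lists. A442M lists were 1.29-fold as long as WT lists (0.36 in log2, higher in 4 of 4 pairs, exact permutation test, p = 0.111) and 1.33-fold as long as G444E lists (4 of 4 pairs, exact permutation test, p = 0.0556). G444E lists were 0.967-fold as long as WT lists (2 of 4 pairs, exact permutation test, p = 0.833). Both mutants together lay 0.16 above WT in log2 peaks (exact permutation test, p = 0.338 over 225 arrangements). None of these single contrasts can go below 0.0556 with 36 arrangements. The difference between mutants and WT was larger without the tag than with it by 0.27 in log2 (permutation test of the interaction, p = 0.185). Exchanged only within replicate numbers, the same interaction gave p = 0.0312, the smallest that permutation allows.

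**Figure D1:**
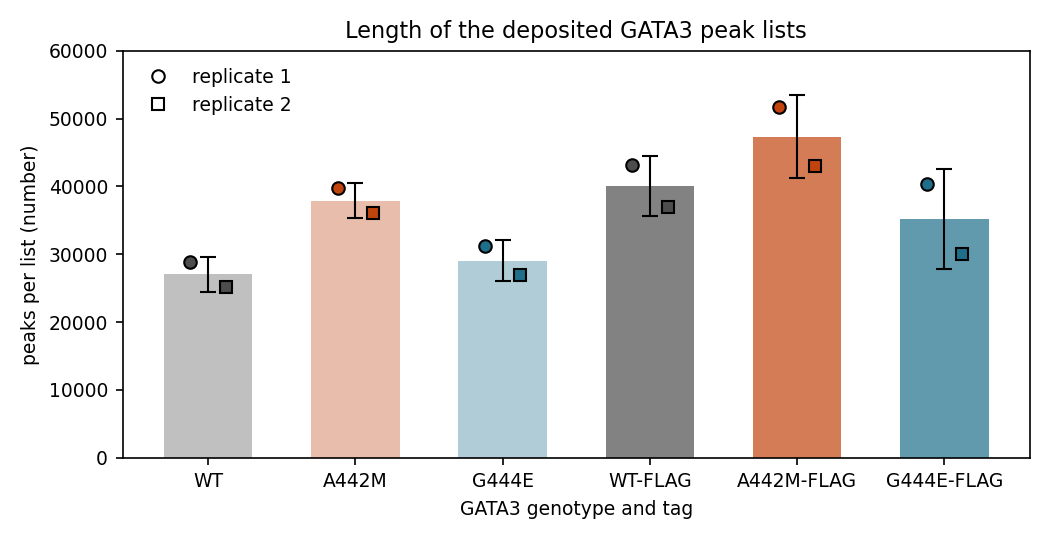
Number of peaks in each deposited list, by GATA3 genotype and tag; bars are group means, error bars 1 SD of 2 libraries, circles replicate 1 and squares replicate 2. FLAG lists averaged 1.30-fold the length of untagged lists, and the untagged WT lists (28890 and 25248 peaks) included the shortest of the 12.

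A region inside the GATA3 gene was called in all 12 libraries. GATA3 lies on chromosome 10 from 8045333 to 8075198, and the shared region, from 8070654 to 8072097, sits inside the gene span, with its centre 3822 bp from the far end. Exons were not assigned, so whether this region lies on coding sequence, to which reads of a GATA3 copy on a vector would also map, is unknown. The next region, 8084644 to 8085197, with its centre 9723 bp beyond the gene, was called in 8 libraries. These were both libraries of G444E, WT-FLAG and G444E-FLAG, 1 of A442M and 1 of A442M-FLAG, and neither untagged WT library. A region at 8100394 to 8100989 was called in 9 libraries and in neither untagged WT library. On the other side of the gene, the region 8026844 to 8027322 was called in both untagged WT libraries, in 1 A442M and 1 WT-FLAG library, and in no other. The remaining 4 regions within 50 kb of the gene ends were called in 1 to 6 libraries. With a score of at least 10, the region at 8026844 was called in 1 library, and with equal lists in 2. These are single regions with no test of their own.

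**Figure D2:**
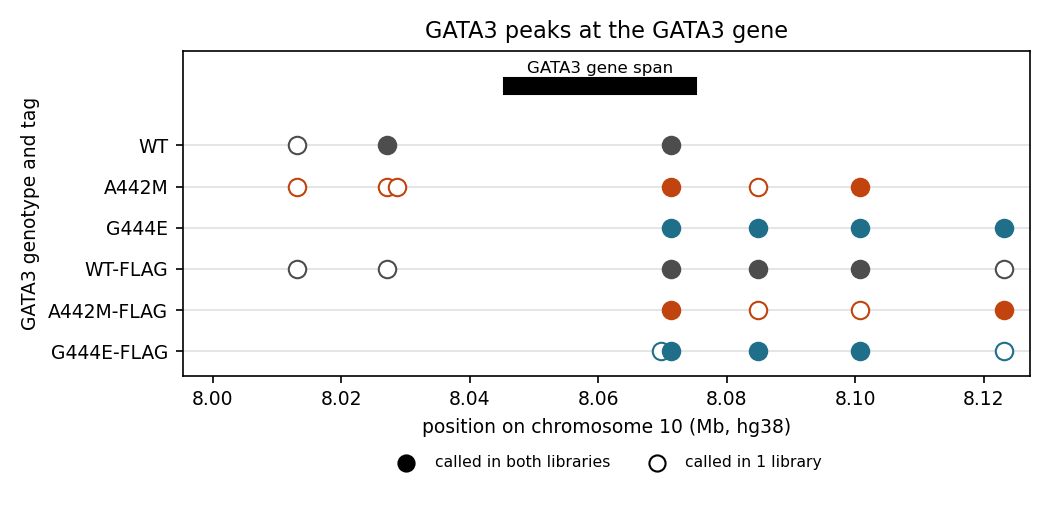
Regions called within 50 kb of GATA3 on chromosome 10 (position in Mb, hg38), one row for each GATA3 genotype and tag; filled circles were called in both libraries, open circles in 1 library, and the black bar is the gene span. The region starting at 8070654 is filled in every row, and the regions starting at 8084644 and 8100394 have no circle in the untagged WT row.

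A common set of regions was called in every group. No background list was compared, so these regions may include signal that does not come from GATA3. Of the 78999 regions, 10933 (13.8%) were called in all 12 libraries and 18590 (23.5%) in 1 library only. The shared regions with the highest scores lay near TFEB, a transcription factor of lysosomal genes, the cell adhesion gene MDGA1, and NR6A1, an orphan nuclear receptor. The region by TFEB (chromosome 6, 41730039 to 41731774) lay inside the gene span, with a lowest percentile of 99.9 over the 12 lists. ECI2, a fatty acid isomerase, MARCHF8, a membrane ubiquitin ligase, and the zinc-finger factor SP6 came next. PLAAT3, the choline transporter SLC44A1, the integrin ITGB3 and the Arf regulator ASAP1 completed the 10 highest. Of all 20037 protein-coding genes, 38.9% had such a region within 50 kb, a share computed after the lists were seen. It was 17 of 24 luminal, 13 of 16 basal and 13 of 18 mesenchymal genes, 19 of 22 Hippo pathway targets, 13 of 15 TGF-beta pathway genes and 10 of 13 GATA family and cofactor genes. It was 6 of 10 AP-1 family, 9 of 15 estrogen response, 10 of 19 breast metastasis, 9 of 17 cell cycle, 9 of 18 ubiquitin and proteasome, 8 of 16 interferon response and 6 of 14 housekeeping genes. Among genes of other cell types it was 5 of 16 T cell, 3 of 17 erythroid, 6 of 15 neuronal and 1 of 15 muscle genes, and differences between lists were not tested.

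Single genes of these lists had many regions. RUNX1, a partner factor of GATA proteins, had 22 regions within 50 kb of its ends, 9 of them called in all 12 libraries. TGFB2, a TGF-beta ligand counted in the Hippo and TGF-beta lists, had 27 regions, 8 of them in all libraries, and its signal transducer SMAD3 had 27 with 8. CDH1, the epithelial cadherin, had 16 regions, 4 of them in all libraries, and CDH2, the mesenchymal cadherin, had 17 with 5. In the T cell list, IL7R had 21 regions with 6 in all libraries, and in the muscle list TTN had 12 with 0.

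On average, peak sets overlapped more within a replicate group than outside it, though G444E, G444E-FLAG and WT-FLAG each overlapped more with another group. The groups differed widely in how much they shared. Mean Jaccard index was 0.0751 higher between replicates than between other libraries (exact permutation test, one-sided, p = 0.00933 over 10395 arrangements). The overlap of untagged WT with other groups was 0.523 for A442M, 0.466 for G444E, 0.424 for G444E-FLAG, 0.403 for WT-FLAG and 0.324 for A442M-FLAG. Untagged G444E overlapped more with G444E-FLAG (0.591) and WT-FLAG (0.565) than with untagged WT. The closest library to each of the 6 libraries of G444E, G444E-FLAG and WT-FLAG belonged to another of these groups and had the same replicate number, as with G444E-FLAG and WT-FLAG replicate 1 (0.671). Genotypes within a tag state were told apart with labels exchanged within replicate numbers (excess 0.0800, exact permutation test, one-sided, p = 0.0278) and not without that restriction (0.0423, exact permutation test, p = 0.0889). This excess pools both tag states. Untagged genotypes overlapped less with each other (0.466 to 0.549) than replicates did (0.566 to 0.606). WT-FLAG and G444E-FLAG overlapped more with each other (0.606) than their own replicates did (0.584 and 0.541), so they were not set apart. Tag states within a genotype were not told apart (excess 0.0891, exact permutation test, one-sided, p = 0.0741, and 0.125 within replicate numbers, the smallest that 8 arrangements allow). The replicate result lost its call without either untagged WT library (exact permutation p = 0.0741 each) or without A442M-FLAG replicate 1 or 2 (exact permutation p = 0.0582 and 0.0593).

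**Figure D3:**
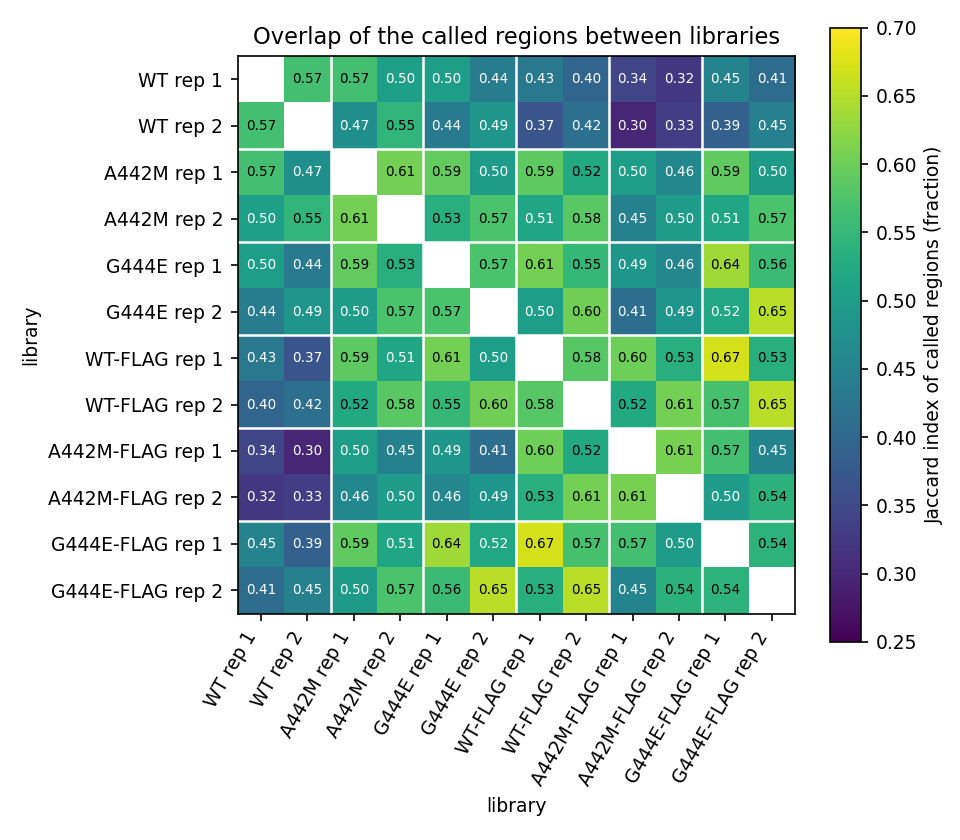
Jaccard index of the called regions for each pair of the 12 libraries (a fraction from 0 to 1, colour scale on the right), with white lines between groups. The lowest values pair untagged WT with A442M-FLAG (mean 0.324) and the highest pairs G444E-FLAG with WT-FLAG replicate 1 (0.671).

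Whether the A442M mutation changes where untagged GATA3 is found was asked first. A442M had 5547 regions in both of its libraries that neither WT library called, and WT had 544 that A442M lacked, while 16869 were called in all 4. The highest ranked A442M region lay inside AOPEP, an aminopeptidase gene (chromosome 9, 94742922 to 94744696), with a lowest percentile of 95.9 in the A442M lists. Most one-sided regions were weaker: the median percentile was 27.6 for A442M and 18.1 for WT, against 69.3 for shared regions in A442M. Further ones lay near SIGLEC5, a lectin of immune cells, TMEM30A, a subunit of lipid flippases, the actin regulator CAP2 and the scavenger receptor SCARF1. CREB3L2, SECISBP2L and the fatty acid elongase ELOVL5 completed the 8. All 8 were called in every library other than the untagged WT ones. In the opposite direction, regions near NOG, an inhibitor of BMP signalling, CDC42SE2 and the plexin PLXNA2 were called in the WT libraries alone, and that near the sialyltransferase ST3GAL3 in WT and 2 other libraries. Of the luminal genes 13 of 24 had an A442M region absent from WT within 50 kb and 0 a WT region absent from A442M. Among mesenchymal genes these counts were 12 and 0 of 18, among T cell genes 5 and 1 of 16, and among neuronal genes 5 and 2 of 15. No such share was computed over all protein-coding genes, here or in the comparisons below. Member counts lean to the group with more one-sided regions, so they cannot be read as particular to a list. With lists of equal length, the region counts were 2476 for A442M and 1444 for WT. Dividing the same 4 libraries by replicate number gave 4405 one-sided regions, and the third, crossed division 743, against 6091 by genotype. Over all 9 pairs of groups the crossed division gave 542 to 1328.

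G444E and untagged WT each had regions that the other lacked. Untagged WT and A442M stood apart from the 4 other groups in peaks on unplaced contigs (means of 97 and 66 against 15 to 21). So this comparison, untagged A442M against G444E, WT-FLAG against WT and A442M-FLAG against A442M cannot be separated from a batch of those libraries. The pooled contrasts of tag and of mutation cross the same divide in part. Untagged WT and A442M also differed from each other on these contigs (110 and 84 peaks against 75 and 57). Untagged A442M against WT therefore cannot be separated from a batch of untagged WT alone. Both G444E libraries called 4018 regions absent from WT, and WT called 2890 absent from G444E, with 13228 in all 4. The region inside AOPEP ranked first again, with a lowest percentile of 98.7, followed by regions near VTA1, a gene of endosomal sorting, SIGLEC5, the phosphatase gene PTPN14 and the kinase gene NEK8. C19orf47, CAP2 and SECISBP2L followed, and all 8 regions were called in every library except untagged WT. The median percentile was 29.9 for all G444E regions absent from WT and 32.7 for the opposite side, against 66.5 for shared regions. The strongest WT regions absent from G444E lay near STARD5, PTGDR, a prostaglandin receptor, the corepressor gene BCOR and ZNF337. The region by STARD5 (chromosome 15, 81265952 to 81266810) lay inside IL16, the span of a cytokine gene, and was called in both A442M libraries too, as were those by BCOR and ZNF337. Luminal genes with a G444E region absent from WT numbered 12 of 24, with 1 the other way. For Hippo targets it was 11 and 1 of 22, and for mesenchymal genes 5 and 4 of 18. With equal lists the counts were 3287 for G444E and 3008 for WT. Dividing the 4 libraries by replicate number gave 3435 one-sided regions, against 6908 by genotype.

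Set against each other without the tag, A442M had 4238 regions absent from G444E and G444E had 705 absent from A442M, with 18128 in all 4. These groups also differed on unplaced contigs (means of 66 and 15), so a batch cannot be separated from the mutation here. Mesenchymal genes with a region on the A442M side numbered 10 of 18, and 0 had one on the G444E side. Interferon response genes also leaned to A442M, with 6 and 0 of 16. Luminal genes had 3 and 3 of 24, Hippo targets 6 and 5 of 22, and breast metastasis genes 3 and 4 of 19. Of the TGF-beta pathway genes 7 of 15 had a region on the A442M side and 3 on the other. With equal lists, 1862 and 1388 regions were one-sided. By replicate number the same libraries gave 4507, against 4943 by genotype.

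With the tag, which the design text describes as stabilising GATA3 whatever the mutation, A442M had the longer lists and more one-sided regions. A442M-FLAG libraries called 4713 regions absent from WT-FLAG, and WT-FLAG 1245 absent from A442M-FLAG, with 24287 in all 4. High ranked A442M-FLAG regions lay near SLC46A2, SYNPO2, USP53, TMED10, HIVEP2 and KIAA1549. The region inside SYNPO2 (chromosome 4, 119055806 to 119056469) was called in the A442M-FLAG libraries alone. Over all one-sided regions the median percentile was 25.7 for A442M-FLAG and 16.0 for WT-FLAG, against 64.3 for shared regions. The strongest WT-FLAG regions absent from A442M-FLAG lay near KMT2C, a histone methyltransferase gene, GSG1L, HHIPL2 and the adhesion receptor ADGRF5. Those by KMT2C, GSG1L and ADGRF5 were called in every library outside A442M-FLAG. Basal genes with a region on the A442M-FLAG side numbered 8 of 16, with 2 the other way, and Hippo targets 9 of 22, with 2. Dividing these libraries by replicate number gave 6383 one-sided regions, more than the 5958 by genotype. With equal lists the counts were 2070 for A442M-FLAG and 1525 for WT-FLAG, so most of the asymmetry went with list length. With calls that cover at least 50% of a region they were 5137 and 1912.

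G444E-FLAG and WT-FLAG were close to each other. G444E-FLAG had 367 regions absent from WT-FLAG, WT-FLAG had 1732 absent from G444E-FLAG, and 21582 were called in all 4. The ranked G444E-FLAG regions lay near TPD52-MRPS28, RAPGEF2, LIMA1 (2 regions), ZSCAN23, OR52B6, GRAMD2B and the kinase gene PRKACB, and their lower percentiles ran from 59.4 to 81.3. On the WT-FLAG side they lay near MAP7D3, ADHFE1, IGHMBP2 and a further site inside AOPEP (chromosome 9, 94746030 to 94746913). Of the luminal genes 0 of 24 had a region on the G444E-FLAG side and 1 on the other. By replicate number the libraries gave 7724 one-sided regions, above the 2099 by genotype. With a score of at least 10 the counts were 242 for G444E-FLAG and 1494 for WT-FLAG, and with equal lists 467 and 623.

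A442M-FLAG had 7111 regions absent from G444E-FLAG, which had 888 absent from A442M-FLAG, with 20768 in all 4. Basal genes with a region on the A442M-FLAG side numbered 12 of 16 (2 the other way), Hippo targets 13 of 22 (4 the other way) and T cell genes 2 of 16 (4 the other way). With equal lists the counts were 2874 and 1851. Dividing the libraries by replicate number gave 6350, against 7999 by genotype.

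**Figure D4:**
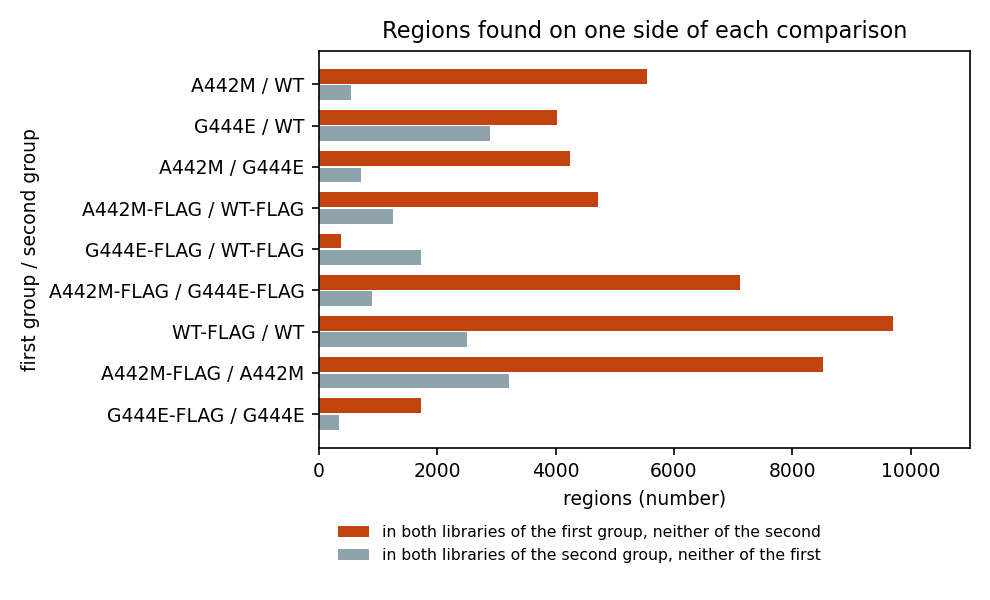
Number of regions called in both libraries of one group and neither of the other, for 9 pairs of groups; red bars belong to the first group named and grey bars to the second. The longest bar is WT-FLAG against WT (9709 regions) and the shortest G444E regions absent from G444E-FLAG (339).

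WT-FLAG against untagged WT gave the highest one-sided count of the 9 comparisons. These groups differed on unplaced contigs (means of 21 and 97), so a batch cannot be separated from the tag here. WT-FLAG libraries called 9709 regions absent from untagged WT, and untagged WT 2507 absent from WT-FLAG, with 14077 in all 4. The region inside AOPEP was first, with a lowest percentile of 99.8 in the WT-FLAG lists, and those by SCARF1, C19orf47, the AMP deaminase gene AMPD2, PRPH2, CAP2, SIGLEC5 and NEK8 followed. All 8 were called in every library except untagged WT. Most of the 9709 regions were weaker, with a median percentile of 34.2 against 70.2 for shared regions. The strongest regions on the untagged side, whose median was 37.7, lay near NCK2, CAMK1D, a calmodulin-dependent kinase gene, TMEM72 and COL26A1, and each was also called in both untagged A442M libraries. Ubiquitin and proteasome genes with a WT-FLAG region absent from WT numbered 12 of 18, with 0 the other way. For luminal genes these counts were 16 and 0 of 24, for basal genes 13 and 1 of 16, and for T cell genes 8 and 1 of 16. By replicate number the 4 libraries gave 3234 one-sided regions, against 12216 by tag. With equal lists, 4832 and 3931 regions were one-sided.

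In A442M cells the tag went with 8512 regions gained and 3208 absent, and in G444E cells with 1728 and 339. Untagged A442M stood apart from A442M-FLAG on unplaced contigs (means of 66 and 18.5), while G444E and G444E-FLAG were alike (15 and 19.5). The larger A442M counts therefore cannot be separated from a batch of the untagged libraries. Luminal genes had tag-side regions at 13 of 24 members in A442M and 4 of 24 in G444E. Equal lists gave 4104 regions with the tag against 3639 without it in A442M, and 664 against 598 in G444E. By replicate number the A442M libraries gave 4370 one-sided regions, against 11720 by tag, and the G444E libraries 6406, above the 2067 by tag.

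No single region passed the adjusted threshold for the tag or for mutation. Of 11777 regions tested for FLAG against untagged, Fisher's exact test called 0 after Benjamini-Hochberg adjustment, with a lowest adjusted p of 0.104. At an unadjusted threshold 1329 regions were called more often in FLAG libraries and 192 less often. All 6 FLAG and no untagged libraries called 230 regions, and the reverse held for 16. Of 26654 regions tested for mutant against WT, 0 passed, and unadjusted 55 were called more often in mutants and 28 less often. Stratified by replicate number, the exact test also called 0 regions in each comparison, with 89 and 41 unadjusted for mutant against WT.

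No gene list passed the threshold after adjustment over the 17 lists, for the tag or for mutation. The exact permutation test could not have passed 1 list alone: its smallest adjusted p is 0.157 for the tag and 0.0756 for mutation, and 4 and 2 lists at the smallest p would be needed. For the tag, 3 lists sat at that smallest p. Ubiquitin and proteasome genes, a list set for the protein degradation theme of the series title, had 0.186% of FLAG peaks within 50 kb and 0.148% of untagged peaks (exact permutation p = 0.00926, adjusted 0.0525, higher in 6 of 6 same-number pairs). Housekeeping genes had 0.104% of untagged peaks and 0.0158 percentage points more of FLAG peaks (exact permutation p = 0.00926, adjusted 0.0525, 6 of 6 pairs). TGF-beta pathway genes had 0.277% against 0.290% (exact permutation p = 0.00926, adjusted 0.0525, lower in 6 of 6 pairs). Estrogen response genes, such as the carbonic anhydrase gene CA12, had 0.178% against 0.156% (exact permutation p = 0.0185, adjusted 0.0787, higher in 5 of 6 pairs).

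The other 13 lists had adjusted p between 0.236 and 0.981 for the tag by exact permutation. FLAG against untagged shares were 0.253% and 0.235% for luminal, 0.257% and 0.238% for basal and 0.218% and 0.217% for mesenchymal genes. They were 0.193% and 0.194% for breast metastasis, 0.0932% and 0.0852% for AP-1 family and 0.428% and 0.414% for Hippo target genes. Cell cycle genes had 0.118% and 0.107%, interferon response genes 0.122% and 0.114%, and GATA family and cofactor genes 0.142% and 0.157%. Among other cell types, T cell genes had 0.103% and 0.105%, erythroid genes 0.0489% and 0.0495%, neuronal genes 0.0657% and 0.0743%, and muscle genes 0.0340% and 0.0263%.

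For mutants against WT the smallest p belonged to neuronal genes, with 0.0648% of mutant and 0.0802% of WT peaks (exact permutation p = 0.0133, adjusted 0.227, higher in 1 of 8 same-number comparisons). Ubiquitin and proteasome genes had 0.174% and 0.153% (exact permutation p = 0.0311, adjusted 0.264, higher in 6 of 8). Luminal genes had 0.247% and 0.238% and mesenchymal genes 0.214% and 0.225%, with adjusted p of 0.815 and 0.803 by exact permutation. The neuronal and ubiquitin differences lay mostly in untagged libraries. For neuronal genes A442M and G444E differed from WT by -0.0257 and -0.0232 percentage points untagged, and by -0.0103 and -0.00235 with the tag. For ubiquitin and proteasome genes the differences were 0.0360 and 0.0368 untagged, and -0.00294 and 0.0116 with the tag.

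Few peaks lay at gene ends in any group. Within 1 kb of an end of a protein-coding gene were 4.39% ± 0.65 of the peaks in WT, 4.70% ± 0.61 in A442M and 5.06% ± 0.84 in G444E (SD, n = 2 each). With the tag the shares were 5.87% ± 1.42, 4.46% ± 0.85 and 5.67% ± 1.48. The tag contrast was 0.62 percentage points (exact permutation p = 0.361) and the mutant contrast -0.16 (exact permutation p = 0.809). With equal lists the tag contrast turned to -0.184, and the mutant contrast turned to 0.0874 at 5 kb.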

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

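The tests chosen only after their results were seen were those of same-number overlap in pairs of groups and with equal lists, of the rank of missing regions and of their calls in A442M, of regions gained or lost with the tag in G444E cells, of the regions lost with the tag in A442M cells, of the ratio of shares in untagged A442M and G444E, and the splits for the adjusted counts. The divisions with replicates kept together and the unadjusted counts themselves were added after the adjusted ones were seen.

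The difference between mutants and WT in log2 peaks was 0.27 larger without the tag than with it, which passed its permutation test only with labels exchanged within replicate numbers (p = 0.0312, against 0.185). G444E lists were longer than WT lists untagged (0.10 in log2, both same-number pairs) and shorter with the tag (-0.20, both pairs), with a permutation p of 0.389 for that interaction. For the share of peaks at gene ends, A442M lay 0.317 percentage points above WT untagged and differed by -1.41 with the tag. G444E lay 0.67 above untagged, with a difference of -0.207 with the tag. The tag itself went with 1.49 points more at gene ends in WT and with a difference of -0.24 in A442M, while G444E differed by 0.61. The gene-end interactions with WT had permutation p-values of 0.222 for A442M and 0.722 for G444E, and the tag difference between A442M and G444E was not tested.

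Peaks on contigs outside the assembled chromosomes are counted in the list lengths and regions above and were not compared on their own. They averaged 97 in WT and 66 in A442M, against 15 in G444E, 21 in WT-FLAG, 18.5 in A442M-FLAG and 19.5 in G444E-FLAG. Peaks on the mitochondrial genome numbered 9 in G444E replicate 1 and 2 in replicate 2, and 0 elsewhere.

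Untagged WT lacked 2061 regions that all 10 other libraries called, against 170 for A442M-FLAG and 71 or fewer for the other groups. Shorter lists go with part of it: equal lists left 1162 such regions for WT and raised A442M-FLAG, the highest other group, to 492. They do not account for all of it, since WT still lacked the most. Weak enrichment stays open: the share missing from WT was 29.8% at percentiles up to 10 and 0.787% above 90, and the 25.4% of missing regions above the median rank of all 10 other lists compares with 28.8% for A442M-FLAG. A batch of untagged WT and A442M cannot be told apart from the genotypes: both groups lacked 261 regions called in all others, the highest of the 15 pairs (next 135), and stood apart on contigs, and the 71.6% of 2880 regions missing from WT and called outside both groups that A442M called are the pattern itself. A higher GATA3 level with the tag and the mutations is a biological hypothesis left open too, since with equal lists G444E exceeded WT by 21.5 points (lost side -32.2) over the regions gained with the tag in A442M cells, which that batch would give, and A442M exceeded WT by 13.3 (lost side -1.92) over those gained in G444E cells, which a batch of untagged WT alone could give; GATA3 levels were not measured here.

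Untagged WT also held 2507 regions that WT-FLAG lacked, and their peaks were narrow: the median width was 0.831 of that of shared regions at the same score percentile in the WT lists. Reads piled up by mapping error or copy number could give narrow peaks, and the ratio lay between the values set for and against that explanation, so it stays open. The lowest share of these regions called in an untagged A442M library was 4.07 times the highest share in an untagged G444E library, which a batch of untagged WT and A442M would give and a common loss with the tag and with G444E would give too. These explanations cannot be told apart, because the design has no second batch of the same groups.

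Libraries of different groups with the same replicate number overlapped more than those with different numbers, in 15 of 15 pairs of groups, as a shared batch behind the numbers would give. The excess of 0.0664 in the Jaccard index was 0.0671 with equal lists and 0.0667 with 500 bp windows, so neither list length nor peak width of the replicates accounts for it. No biological explanation was tested, since the design names none.

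For FLAG against untagged, 0 regions passed the adjusted threshold in the real grouping and in each of 99 others drawn from 462; a count of 0 is reached by any grouping (100 of 100), so this says nothing on chance. The unadjusted count of 1521 was reached by 1 of 100, the real one, and the highest other was 848 (751 among the 40 that hold both numbers equally), so chance is excluded for random groupings of single libraries. With replicates kept together only 10 divisions exist, too few for a share under 0.05, and the real one gave 1521 against at most 622. Dividing the libraries by replicate number, whose meaning the labels do not give, gave 1788, above the real count, and the test stratified by number called the same 1329 and 192 regions. For mutant against WT, 0 regions passed in all 100 groupings of 495 possible, which again says nothing on chance. The unadjusted count of 83 was reached by 73 of 100, so chance cannot be excluded. The highest other was 1284 (1236 among the 43 that hold both numbers equally). That grouping set A442M replicate 2, WT-FLAG replicate 2 and both A442M-FLAG libraries against the rest. It holds mostly A442M libraries, but also mostly FLAG libraries and mostly libraries of replicate 2, so it does not tell these apart.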

How the results depend on the processing

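The alternatives here were set before the data were examined. The longer FLAG lists kept their direction and their call in every alternative that applies (a score of at least 10, the replicate block and each library left out), with differences of 0.31 to 0.45 in log2 peaks. The counts of 0 regions and 0 gene lists past the adjusted threshold stayed 0 in the alternatives run for them, which says nothing on stability, since 1 changed list could not pass with or without the replicate block and 200 simulated changed regions were not called. Motif shares and their alternatives were not run, and peak number has no value for lists of equal length. With the replicate block, that is, labels exchanged within a replicate number, the interaction on peak number (0.27) went from p = 0.185 to p = 0.0312 and the genotype overlap excess (0.0800) to p = 0.0278 by exact permutation; it changed no other call. A score of at least 10 also took the genotype excess past the threshold (0.0559, exact permutation p = 0.0267) and gave 242 regions for G444E-FLAG and not WT-FLAG. With each library left out, the genotype excess ran from 0.0235 to 0.0656, past the threshold without either WT-FLAG library, and the excess between replicates from 0.0396 to 0.0985, no longer past it without either untagged WT or either A442M-FLAG library. The gene-end share of mutants against WT, -0.16 percentage points, turned to 0.0874 at 5 kb, to 0.0710 without WT replicate 1, to 0.346 without WT-FLAG replicate 1 and to 0.0435 without A442M-FLAG replicate 2, and ran from -0.661 to 0.346 over the libraries left out; the tag contrast turned to -0.184 with equal lists. None of these gene-end contrasts passed its test, and the cause was not tested. The G444E interaction ran from 0.0865 to 0.514 for log2 peaks and from -0.173 to 1.93 for the gene-end share. One-sided region counts moved most, as they depend on list length by construction. Equal lists gave 2476 and 1444 for A442M against WT, 1862 and 1388 for A442M against G444E, 2070 for A442M-FLAG and not WT-FLAG, 623 for WT-FLAG and not G444E-FLAG, 2874 and 1851 for A442M-FLAG against G444E-FLAG, 4832 and 3931 for WT-FLAG against WT, 4104 for A442M-FLAG and not A442M, and 664 and 598 for G444E-FLAG against G444E. Calls covering at least 50% of a region gave 1912 for WT-FLAG and not A442M-FLAG, and 500 bp windows moved no count by over 1.5 times. Asking for a call in at least 1 library, a looser rule, gave 16877 and 4556 for A442M against WT, 12517 and 10113 for G444E against WT, 15219 and 5302 for A442M against G444E, 16383 and 8408 for A442M-FLAG against WT-FLAG, 6111 and 11169 for G444E-FLAG against WT-FLAG, 20071 and 7038 for A442M-FLAG against G444E-FLAG, 24144 and 8149 for WT-FLAG against WT, 22225 and 10576 for A442M-FLAG against A442M, 12456 and 3923 for G444E-FLAG against G444E. Leaving out a library loosens the rule in the same way and gave 7658 to 12042 and 1156 to 2956 for A442M against WT, 5332 to 9187 and 3894 to 7210 for G444E against WT, 6238 to 10527 and 1464 to 3484 for A442M against G444E, 7270 to 12475 and 2407 to 5849 for A442M-FLAG against WT-FLAG, 1384 to 4603 and 3458 to 7366 for G444E-FLAG against WT-FLAG, 9299 to 15539 and 1795 to 5433 for A442M-FLAG against G444E-FLAG, 11731 to 18775 and 3354 to 5844 for WT-FLAG against WT, 10950 to 17723 and 4349 to 7396 for A442M-FLAG against A442M, 3603 to 9488 and 896 to 2389 for G444E-FLAG against G444E. Read depth is unknown, so it could not be separated from list length.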

Other observations

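The measure in this part was chosen after the data were seen. A larger share of the peaks lay within 50 kb of a gene in FLAG libraries than in untagged ones, while the contrast within 1 kb did not pass its test. Within 50 kb of an end of any protein-coding gene were 57.4% ± 0.77 of the peaks in WT, 59.1% ± 0.71 in A442M and 62.3% ± 0.80 in G444E (SD, n = 2 each). With the tag these shares were 63.1% ± 1.12, 62.2% ± 1.04 and 63.4% ± 1.62. The tag contrast was 3.32 percentage points (exact permutation p = 0.0185, higher in 6 of 6 same-number pairs), and it kept its call in every alternative run, with values from 2.91 to 3.70. It came mostly from WT (5.75 points) and A442M (3.12), against 1.08 in G444E, and the differences between genotypes were not tested. WT and A442M are also the genotypes whose untagged libraries stood apart on unplaced contigs. A batch of those libraries could give the same pattern, so the tag contrast cannot be separated from it. Mutants against WT differed by 1.51 points (exact permutation p = 0.196).

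Untagged WT and A442M libraries also had a higher share of their peaks on the X chromosome, with 3.02% ± 0.044 and 3.03% ± 0.024, than the other groups, whose means ran from 2.53% to 2.66%. A442M-FLAG had 3159 regions called in both of its libraries and in no other library, against 391 for untagged WT, 245 for A442M, 105 for WT-FLAG, 38 for G444E-FLAG and 7 for G444E. Its lists were also the longest (51694 and 42993 peaks), and such counts depend on list length.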
